A study of Homo sapiens with 10 samples.

How the data were processed

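The text describes 10 libraries of poly(A)-selected RNA from the A375 line, made with a directional kit and sequenced as single reads of 100 nt, per the labels' protocols. The labels place 4 PHF10 knockdown libraries and 2 controls in experiment 1 and 2 MYC knockdown libraries and 2 controls in experiment 2, each experiment with its own controls. The titles of the PHF10 samples contain the word total, whose meaning is not given in the sources used here. Reads were trimmed with cutadapt and aligned and counted per gene with STAR against GRCh38.p13 (hg38), per the submitters' processing notes. The versions of both tools and the gene annotation are not given in the sources used here. The deposited values are raw read counts for 60623 Ensembl gene IDs in each library, in an unstranded and 2 stranded columns.

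The column for reads on the opposite strand was used, by a rule fixed before the data were examined, because it held more gene reads than the same-strand column in every library. The same-strand column held 5.27% to 5.55% of the stranded gene reads. Summary lines for reads outside genes, at several places or not aligned made up 19.1% to 23.6% of a library and stayed out of library sizes. Gene names and coordinates came from a table of gene names (60295 IDs) and from GENCODE release 29 (58516 IDs), and 19 IDs had neither. Total reads were 26.1 to 47.6 M per library, and 20.5 to 38.4 M were assigned to genes in the column used. The 10 most abundant genes took 4.79% to 7.79% of those. Replicates of a group correlated with Pearson's r of 0.961 to 0.982 in experiment 1 and of 0.994 and 0.995 in experiment 2 (log2 CPM, prior count 2).

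Counts were fitted in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with TMM factors, a filter by group (filterByExpr) and robust estimates of the spread. All 10 libraries entered as 4 group means, leaving 6 residual degrees of freedom, and 18450 genes were tested. Pooling both experiments gave the groups of 2 a shared spread, which lay above that of experiment 2 alone and below that of experiment 1 alone. A gene was called past the threshold at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were PHF10 knockdown with the controls of experiment 1, the libraries labelled MYC knockdown with the controls of experiment 2, the difference of these 2 effects, and the controls of experiment 2 with those of experiment 1. All log2 fold changes and SE are from this fit unless another is named. CPM values are counts over TMM-scaled library sizes, with the SD across the libraries of a group.

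Gene lists were written from general knowledge before the data were examined and matched by symbol, of which 1135 matched and 2 did not. The 34 lists covered PBAF and BAF subunits, the MYC-MAX-MXD network, nucleolar and ribosome biogenesis factors, other classical MYC targets, nucleotide synthesis, serine and amino acid response (ATF4), cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs and glycolysis. They also covered G1/S and DNA replication, G2/M and mitosis, p53 targets and CDK inhibitors, apoptosis regulators, melanocyte lineage, dedifferentiated melanoma, ERK pathway output, immediate early genes, extracellular matrix and mesenchymal genes, TGF-beta and SMAD targets, type I interferon, NF-kB and inflammatory genes, HLA and antigen presentation and cholesterol and fatty acid synthesis. The rest were hypoxia, endoplasmic reticulum stress, heat shock, lysosome and autophagy, replication-dependent histones, epithelial, immune, endothelial and fibroblast markers, and neural crest and neuronal genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 34 lists of a comparison, and again with an estimated correlation and with fry. Both camera forms ask whether a list differs from the other genes, and an estimated correlation widens the error where members vary together between replicates.

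The genes named in the text followed a rule fixed before the data were examined. It took PHF10 and MYC, the 10 largest rises and the 10 largest falls of each knockdown past the threshold with a mean of at least 5 CPM and no overlap between the groups, and up to 4 members of each list with the smallest unadjusted p. It also took the 6 genes with the largest smaller fold in each pair of directions past the threshold in both, and the 5 at each end of the difference. Clone and locus names were left out, and some genes were left out for length. Genes named for the difference between controls, and in the paragraphs on the structure of experiment 1, were chosen after their values were seen. So were SLC7A5, SLC3A2 and LCP1 where the difference of responses is given, and LCP1 and KRT7 among genes that went opposite ways.

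Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter and a stricter one (1 CPM in 4 libraries), the unstranded column, each experiment alone, the replicate number as a block, a fold threshold of 1.5, and each library left out in turn. With 1 library left out of a group of 2, the lone sample was assumed to vary like the other groups. A split of experiment 1 at the median share of reads outside genes, as a term or as parts, and lists without members shared with the G1/S list were chosen after seeing the data. Each test was tested on simulated counts with 100 genes changed by a fold of 2 and 100 by a fold of 4. For the PHF10 knockdown comparison (18450 genes) edgeR recovered 62% and 95% of them, with 8 of 165 calls wrong, and for the MYC knockdown comparison (18450 genes) 43% and 94%, with 15 of 152 wrong. DESeq2 recovered 77% and 99% for PHF10 knockdown with 40 of 216 calls wrong, and limma 52% and 93% with 9 of 154 wrong. The simulated libraries of both experiments shared 1 pooled spread per gene and held no split. The real experiments differed in spread (26.8% and 3.39%), so these rates need not hold for the data.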

Results

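Messenger RNA was measured by sequencing in A375, a human melanoma cell line with an activating BRAF mutation, after small interfering RNA (siRNA) against PHF10 or against MYC. PHF10 is a subunit of PBAF, a complex that moves and evicts nucleosomes, and MYC is a transcription factor that activates genes of growth and division. Per the series description, the question was what part PHF10 plays in transcriptional activation by MYC. The 10 libraries came from 2 experiments, all harvested 72 h after transfection. Experiment 1 held 4 PHF10 knockdown and 2 control libraries, and experiment 2 held 2 libraries labelled MYC knockdown and 2 control libraries. The labels disagree about the controls, because the protocol describes a control siRNA while the treatment field of the control samples gives no treatment. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

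Reads assigned to genes numbered 21.04, 23.22, 26.98 and 23.38 M in PHF10 knockdown replicates 1 to 4, and 20.47 and 23.71 M in the controls of experiment 1. They numbered 38.37 and 30.01 M in the libraries labelled MYC knockdown, and 36.56 and 33.15 M in the controls of experiment 2. Between 16498 and 17647 genes had at least 10 reads in a library, and 18450 genes were tested. The spread between replicates differed greatly between the experiments. Fitted alone, experiment 1 had a common biological coefficient of variation of 26.8% and experiment 2 one of 3.39%, against 21.4% for both together. Within experiment 1 the type I interferon genes split the libraries across both groups. The mean log2 CPM (gene counts scaled to 1 M reads) of that list of 43 genes was 7.63, 7.33, 3.80 and 4.98 in PHF10 knockdown replicates 1 to 4, and 7.96 and 4.84 in control replicates 1 and 2. This split ran alongside the share of reads outside annotated genes, which was 12.1% to 13.8% in the 3 libraries with high interferon genes and 9.93% to 10.6% in the other 3. Each part of the split held libraries of both groups, and the log2 fold changes after PHF10 knockdown in the 2 parts correlated across all genes with Pearson's r of 0.619.

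PHF10 mRNA fell in every library of its own knockdown. It measured 16.1, 17.96, 15.1 and 15.7 CPM in PHF10 knockdown replicates 1 to 4 against 40.1 and 36.6 CPM in the controls, a log2 fold change of −1.24 (SE 0.10; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00105; n = 4 and 2). PHF10 (ENSG00000130024) lies on chromosome 6 from 169703905 to 169725566 and MYC (ENSG00000136997) on chromosome 8 from 127735434 to 127741434 in GRCh38. MYC mRNA did not separate the groups of experiment 2. It measured 16.7 and 13.3 CPM in the libraries labelled MYC knockdown against 14.9 and 26.5 CPM in the controls, a log2 fold change of −0.46 (SE 0.39; adjusted p = 0.688; n = 2 and 2), and 0.00 without control replicate 2. The labelled library with 16.7 CPM thus held more MYC mRNA than the control with 14.9 CPM, and every direction drawn from this comparison rests on the labels. After PHF10 knockdown MYC measured 12.9, 9.69, 14.6 and 22.0 CPM against 20.2 and 32.1 CPM, a log2 fold change of −0.82 (SE 0.33; adjusted p = 0.174) that was not past the threshold. PHF10 itself measured 124 and 119 CPM in the libraries labelled MYC knockdown and 124 and 125 CPM in their controls (log2 fold change −0.03, adjusted p = 0.942).

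**Figure D1:**
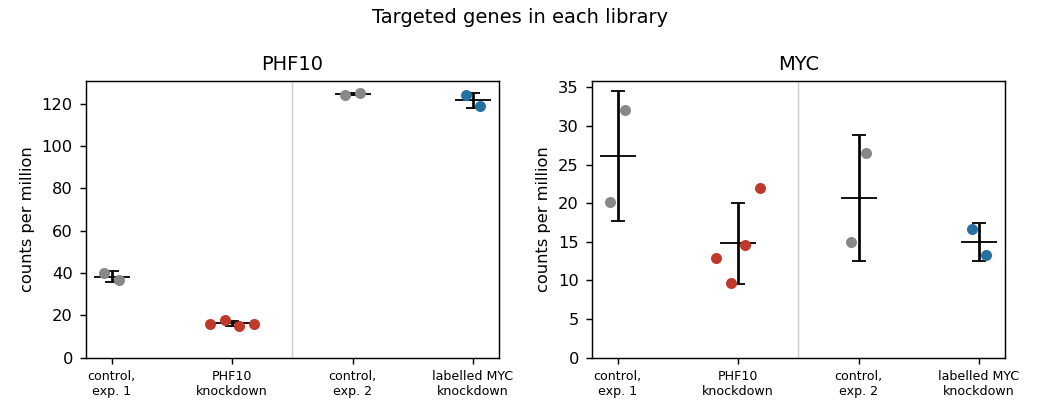
CPM (vertical axes, starting at 0) of PHF10 and MYC in each of the 10 libraries by group, with group means and SD as bars. The 4 PHF10 knockdown libraries lie between 15.1 and 17.96 CPM of PHF10, below their controls at 36.6 and 40.1, while the MYC values of experiment 2 overlap.

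PHF10 knockdown was compared with the controls of experiment 1 to find which genes depend on PHF10. GINS1, a subunit of the replicative helicase, fell by 1.48 on the log2 scale (SE 0.12, adjusted p = 0.00105), from 39.4 ± 3.5 CPM (SD, n = 2) to 14.1 ± 1.4 CPM (SD, n = 4). The checkpoint adaptor CLSPN fell by 1.33 (SE 0.13), BRCA1 by 1.07 (SE 0.12) and the DNA helicase HELLS by 1.03 (SE 0.12). Of the 61 tested members of the G1/S and DNA replication list all had a negative fold change, 47 fell by the edgeR test over all genes and 57 adjusted over the list alone, but only 4 fell with experiment 1 fitted alone. The median log2 fold change of that list was −0.94, and it lay below other genes by camera with a preset correlation (adjusted p = 3.6e-56; adjusted p = 0.41 with an estimated correlation). By fry, which tests whether the genes of a list move one way on balance, its adjusted p was 0.0151. The list's median was −1.14 in the part of the split with high interferon genes and −0.79 in the other.

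All 77 members of the G2/M and mitosis list had a negative fold change, 30 fell over all genes and 61 adjusted over the list alone, but only 1 with experiment 1 fitted alone, with a median of −0.84 (camera adjusted p = 2.3e-38; adjusted p = 0.60 with an estimated correlation and 0.0766 by fry). The median was −1.04 in the part of the split with high interferon genes and −0.75 in the other. Libraries of 1 group also differed between these parts, by −0.71 within PHF10 knockdown and −0.41 within the controls. The list's mean log2 CPM was 4.48 to 5.25 in the PHF10 knockdown libraries and 5.48 and 5.90 in their controls. The kinesin KIF18B fell by 1.46 (SE 0.15). SKA1 fell by 1.44 (SE 0.21), CDCA5 by 1.22 (SE 0.20) and KIF11 by 1.02 (SE 0.14). These 3 missed the threshold with 1 control left out: SKA1 without control replicate 1 (adjusted p = 0.0581), KIF11 without control replicate 2 (0.0506), and CDCA5 without either (0.0588 and 0.0761).

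Lists tied to MYC lay lower by smaller amounts. Nucleotide synthesis had a median of −0.47 with 7 of 28 genes lower over all genes and 14 adjusted over the list alone (camera adjusted p = 1.3e-09; adjusted p = 0.68 with an estimated correlation). ADSS2 fell by 0.77 (SE 0.10) and RRM2 by 1.23 (SE 0.18). The list of other classical MYC targets had a median of −0.22 with 7 of 48 genes lower over all genes and 11 adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.68 with an estimated correlation). Its member E2F1 fell by 1.20 (SE 0.17), EZH2 by 0.71 (SE 0.12) and TERT by 1.51 (SE 0.27). With experiment 1 fitted alone 0 genes of either list passed by edgeR, although both lists did. Without the 5 members each shares with the G1/S and DNA replication list, a choice made after the values were seen, their medians were −0.34 and −0.20 (camera adjusted p = 2.7e-07 and 4.1e-06). Without control replicate 1 the median of the MYC targets was −0.42 and without replicate 2 it was −0.10, while nucleotide synthesis had −0.29 without replicate 2. RRM2, EZH2 and TERT missed the threshold without control replicate 1 (adjusted p = 0.0501, 0.0692 and 0.110) and without replicate 2 (0.0576, 0.0783 and 0.0580). Nucleolar and ribosome biogenesis factors had a median of −0.25 with 2 of 60 genes lower over all genes and 1 adjusted over the list alone (camera adjusted p = 6.7e-06; adjusted p = 0.69 with an estimated correlation). Between the high and low parts of the split, PHF10 knockdown libraries differed by similar amounts, −0.41, −0.32 and −0.25 on these lists in turn. Their controls differed by −0.33, −0.26 and −0.23. Median fold changes within the parts were −0.47 and −0.44, −0.27 and −0.23, and −0.28 and −0.23. Alone among these lists, ribosome biogenesis overlapped between the groups in mean log2 CPM (6.57 in PHF10 knockdown replicate 4, 6.53 in control replicate 1). That list missed the threshold without control replicate 2 (median −0.13, adjusted p = 0.0686), and 0 of its genes passed by edgeR with experiment 1 fitted alone.

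The MYC-MAX-MXD network itself had a median of −0.07 and a mean of 0.09, and did not pass (camera adjusted p = 0.469). By edgeR 0 of its 20 members passed, with 3 lower at an unadjusted p under 0.05 and 0 by DESeq2 or limma. Cytosolic ribosomal proteins had a median of 0.13 and did not pass (adjusted p = 0.139), and 0 of 78 were past the threshold by edgeR, DESeq2 or limma, or at an unadjusted p under 0.05. With the split of experiment 1 as a term, chosen after seeing the data, that list passed (adjusted p = 0.00158) with 14 genes higher. PBAF and BAF subunits had a median of −0.11 (camera adjusted p = 0.0497; adjusted p = 0.68 with an estimated correlation). This list includes PHF10 itself, the target of the siRNA, and was not tested without it. Its median was −0.08 in the part of the split with high interferon genes and −0.14 in the other. In that list 1 gene was higher and 2 lower over all genes, and 1 and 3 adjusted over the list alone. Besides PHF10, ARID1A fell by 0.44 (SE 0.11) and BICRAL rose by 0.66 (SE 0.15). The list missed the threshold without PHF10 knockdown replicate 1 (median −0.059, adjusted p = 0.0859), replicate 2 (0.0698) or control replicate 2 (median −0.049, adjusted p = 0.262), had a median of −0.17 without control replicate 1, and missed it also by limma, with RLE or upper-quartile factors, with a stricter filter or unstranded counts, and with experiment 1 fitted alone. ARID1A missed it without PHF10 knockdown replicates 1, 2 or 4 or either control (0.0525 to 0.253), and BICRAL without PHF10 knockdown replicate 4 or either control (0.0504 to 0.188).

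Among the largest rises, PTHLH, which encodes parathyroid hormone-like hormone on chromosome 12 (27958084 to 27972705), rose by 3.39 (SE 0.23, adjusted p = 0.000589), from 2.45 ± 0.28 CPM (SD, n = 2) to 25.6 ± 5.4 CPM (SD, n = 4). The proton pump subunit ATP6V0A4 rose by 3.53 (SE 0.31), from 7.61 ± 1.6 to 88.1 ± 27 CPM. ADGRF1 rose by 2.29 (SE 0.25) and RAB27B by 2.26 (SE 0.21), and these 4 passed with any 1 library left out. LURAP1L, PDE2A, GPRC5C, STC1, WNT9A and SORBS2 rose by 2.30 to 3.55, and all 6 missed the threshold without control replicate 1 (adjusted p = 0.0928 to 0.151) or without control replicate 2 (0.0640 to 0.240). GPRC5C also missed it without PHF10 knockdown replicate 3 (0.0537) and STC1 without replicate 4 (0.0540).

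Among the largest falls, OLFML3 fell by 2.12 (SE 0.27), from 33.5 ± 6.8 to 7.7 ± 2.5 CPM. CADM3 fell by 1.93 (SE 0.22), COL5A3 by 1.89 (SE 0.29), PRSS33 by 1.68 (SE 0.19), TBXAS1 by 1.65 (SE 0.14) and HKDC1 by 1.58 (SE 0.21). SERPINF1 fell by 1.98 (SE 0.28), ITGA9 by 1.85 (SE 0.30) and CHRDL1 by 1.81 (SE 0.41), and these 3 missed the threshold without control replicate 2 (adjusted p = 0.0651, 0.103 and 0.358). CHRDL1 also missed it without PHF10 knockdown replicate 1 (0.0710) or replicate 3 (0.0546). PTN fell by 1.51 (SE 0.21) and missed it without control replicate 1 (0.0581).

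In all, 508 genes rose and 661 fell after PHF10 knockdown, of which 249 and 226 changed by at least 1 on the log2 scale, and 4184 genes had an unadjusted p under 0.05 against 922 expected by chance. The counts depended on the controls, with 79 and 127 without control replicate 1 and 68 and 150 without control replicate 2. With experiment 1 fitted alone they were 23 and 27, all of them among the 1169, and they held 4 of the 10 largest rises and 4 of the 10 largest falls. That fit gave 2858 genes at an unadjusted p under 0.05. Its spread was 26.8%, against 21.4% in the fit of both experiments, so the pooled p-values of this comparison used a spread below its own.

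The amino acid transporter SLC7A5 rose by 1.45 (SE 0.15), SLC7A11 by 0.92 (SE 0.10) and SLC3A2 by 0.86 (SE 0.11), in a serine and amino acid response (ATF4) list whose median of 0.11 did not pass (camera adjusted p = 0.0821). There 4 of 27 genes rose and 1 fell over all genes, and 5 rose and 2 fell adjusted over the list alone. Its median ran from −0.02 without PHF10 knockdown replicate 1 to 0.41 without control replicate 1, and the list passed without that control, by DESeq2, with a stricter filter and in the part of the split with low interferon genes. BTG2 rose by 1.59 (SE 0.18) in the list of p53 targets and CDK inhibitors, which had a median of 0.20 with 2 of 32 genes higher over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0451; adjusted p = 0.69 with an estimated correlation). NF-kB and inflammatory genes had a median of 0.22 with 4 of 25 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0290; adjusted p = 0.69 with an estimated correlation). LIF in that list rose by 0.89 (SE 0.17) but missed the threshold without control replicate 2 (adjusted p = 0.145). Lysosome and autophagy genes had a median of 0.14 with 4 of 42 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0392; adjusted p = 0.69 with an estimated correlation), among them NPC1, which rose by 0.65 (SE 0.12) but missed the threshold without control replicate 2 (0.143). All 3 lists that passed here missed the threshold without control replicate 2 (0.113, 0.611 and 0.0612). The p53 list also missed it without PHF10 knockdown replicate 1 (0.0591) or 2 (0.0957), the NF-kB list without replicate 1 (0.0708), and the lysosome list without replicate 2 (0.165) or 3 (0.0622). The NF-kB list also missed it by limma, and the p53 and lysosome lists with experiment 1 fitted alone, where 1 gene of the p53 list and 0 of the other 2 lists passed by edgeR. With the replicate number as a block the lysosome list missed it too. Medians in the parts of the split with high and low interferon genes were 0.26 and 0.11 (p53), 0.18 and 0.51 (NF-kB), and 0.145 and 0.115 (lysosome). The median of the NF-kB list also moved with single libraries, to 0.44 without PHF10 knockdown replicate 3, 0.35 without replicate 4, 0.68 without control replicate 1 and 0.11 without control replicate 2. That of the lysosome list moved to 0.22, 0.063 and 0.085 without PHF10 knockdown replicates 1, 2 and 3.

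The other 22 lists did not pass after PHF10 knockdown. With the split as a term 8 of them did, namely type I interferon (adjusted p = 0.00279), HLA and immediate early genes (0.0243 for both), cholesterol and fatty acid synthesis (0.0353), neural crest and neuronal genes (0.0447), and endoplasmic reticulum stress, heat shock and fibroblast markers (0.0474 for all 3). ITGA2 rose by 2.09 (SE 0.26) within an extracellular matrix and mesenchymal list of median 0.14, where 7 of 49 genes rose and 4 fell over all genes, and 11 and 8 adjusted over the list alone. The medians were −0.15 for cholesterol and fatty acid synthesis, −0.35 for type I interferon, −0.33 for HLA and antigen presentation, −0.20 for heat shock, −0.14 for glycolysis, −0.12 for endoplasmic reticulum stress and −0.02 for hypoxia. They were 0.08 for nuclear-encoded oxidative phosphorylation, 0.12 for mitochondrially encoded mRNAs, 0.04 for apoptosis regulators, 0.25 for immediate early genes, 0.23 for TGF-beta and SMAD targets and 0.27 for replication-dependent histones, a check on poly(A) selection. The median of type I interferon was 2.04 without control replicate 1 and −1.18 without replicate 2, and that of cytosolic ribosomal proteins −0.17 and 0.53. HLA turned likewise, to 0.45 and −0.67. Over all settings the medians ran from −0.20 to 0.43 for mitochondrially encoded mRNAs, −0.10 to 0.26 for nuclear-encoded oxidative phosphorylation, −0.34 to 1.42 for histones and 0.02 to 0.45 for immediate early genes. Those of glycolysis, hypoxia, melanocyte genes, neural crest and neuronal genes, dedifferentiated melanoma and ERK pathway output also lay on both sides of 0. The range was −0.28 to −0.02 for cholesterol and fatty acid synthesis, −0.28 to −0.04 for heat shock and −0.20 to −0.05 for endoplasmic reticulum stress. It was 0.0002 to 0.23 for apoptosis regulators and 0.15 to 0.42 for TGF-beta and SMAD targets. Melanocyte genes had a median of −0.13, and neural crest and neuronal genes one of −0.09. Markers of epithelial, immune and endothelial cells and of fibroblasts had medians of 0.34, 0.63, 0.32 and 0.49, which ran over all settings from 0.24 to 0.61, 0.06 to 0.88, −0.03 to 0.70 and 0.35 to 0.67. Dedifferentiated melanoma genes and ERK pathway output had medians of 0.02 and 0.07 and means of 0.11 and 0.13, while the test pointed down (camera adjusted p = 0.828 for both). Of the 9 lists that passed, 0 did so by camera with an estimated correlation and 1 by fry.

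**Figure D2:**
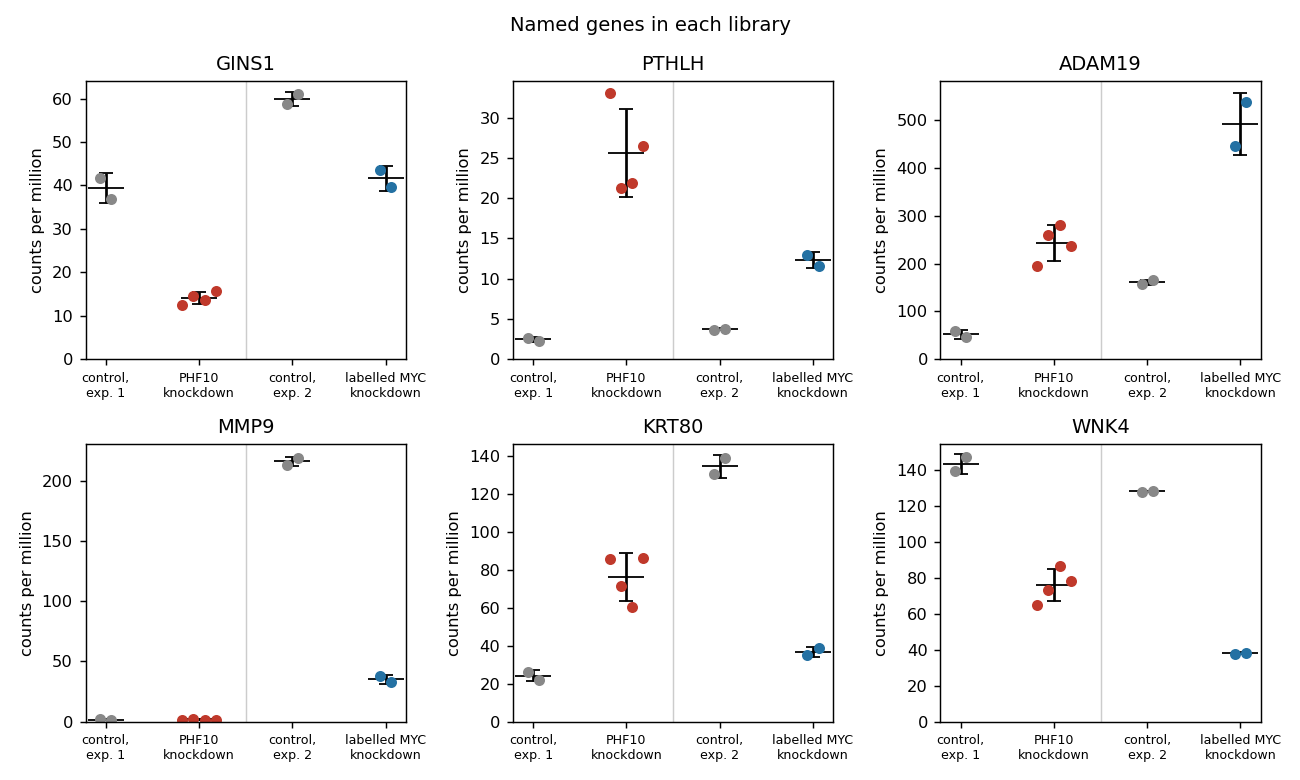
CPM in each library, on a linear vertical axis, of GINS1, PTHLH, ADAM19, MMP9, KRT80 and WNK4 by group. PTHLH and ADAM19 lie higher after PHF10 knockdown and in the libraries labelled MYC knockdown, while KRT80 lies higher after PHF10 knockdown and lower in the libraries labelled MYC knockdown.

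The libraries labelled MYC knockdown were compared with the controls of experiment 2 to find which genes depend on MYC. The gelatinase MMP9 fell by 2.61 on the log2 scale (SE 0.23, adjusted p = 0.0063), from 216 ± 3.7 to 35.3 ± 3.6 CPM (SD, n = 2 and 2). The actin bundler LCP1 fell by 2.33 (SE 0.23), COL5A3 by 2.13 (SE 0.36), MMP8 by 2.05 (SE 0.30), the nerve growth factor receptor NGFR by 1.99 (SE 0.30) and VDR by 1.86 (SE 0.33). KRT80, on chromosome 12 (52168996 to 52192000), fell by 1.87 (SE 0.19), from 135 ± 5.9 to 36.9 ± 2.6 CPM. KRT14 and SDC4 fell by 1.77 (SE 0.28 and 0.17), and WNK4 by 1.75 (SE 0.14, adjusted p = 0.00519), from 128 ± 0.29 to 38 ± 0.57 CPM.

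Among the rises, the netrin receptor UNC5D rose by 3.26 (SE 0.33, adjusted p = 0.0065), from 2.08 ± 0.57 to 20 ± 3.4 CPM (SD, n = 2 and 2). The neurotensin receptor NTSR1 rose by 2.52 (SE 0.26), from 12.3 ± 1.1 to 70.2 ± 9 CPM. PTHLH rose by 1.72 (SE 0.23), AGAP2 by 1.65 (SE 0.27), ADAM19 by 1.61 (SE 0.20), TMEM255B by 1.58 (SE 0.23) and CHRM3 by 1.52 (SE 0.17). The metalloproteinase inhibitor TIMP1 rose by 1.37 (SE 0.16), ELMOD1 by 1.35 (SE 0.22) and PGM2L1 by 1.33 (SE 0.20). MXI1, which competes with MYC for MAX, rose by 1.21 (SE 0.17).

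In all, 52 genes rose and 39 fell, 38 and 31 of them by at least 1 on the log2 scale, and 2435 genes had an unadjusted p under 0.05 against 922 expected by chance. With experiment 2 fitted alone, where replicates lay much closer together, 3790 genes rose and 3989 fell, among them all 91. The fit of both experiments gave this comparison a spread of 21.4%, against 3.39% for experiment 2 alone. With any 1 of the 4 libraries of experiment 2 left out of the edgeR fit of both experiments, 0 genes passed, with 1138 to 1414 at an unadjusted p under 0.05. All 20 named largest changes kept their sign in those fits, at adjusted p of 0.0866 to 0.508. On all libraries DESeq2 gave 354 and 366 genes and limma 128 and 80.

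Genes of growth lay lower as groups in the libraries labelled MYC knockdown, by small amounts each. In the G1/S and DNA replication list 60 of 61 genes had a negative fold change, with a median of −0.38 (camera adjusted p = 4.9e-12; adjusted p = 0.60 with an estimated correlation). Over all genes 0 of them passed by edgeR and 2 fell adjusted over the list alone. At an unadjusted p under 0.05 there were 17, by DESeq2 4 and by limma 0, and 58 with experiment 2 fitted alone. Nucleolar and ribosome biogenesis factors had a negative fold change in 60 of 60 genes and a median of −0.31 (camera adjusted p = 1.6e-09; adjusted p = 0.61 with an estimated correlation). There 0 passed by edgeR, whether over all genes or adjusted over the list alone, with 16 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma and 50 with experiment 2 fitted alone. Nucleotide synthesis had a median of −0.40 (camera adjusted p = 8.7e-08; adjusted p = 0.60 with an estimated correlation). By edgeR 0 of 28 passed over all genes and 3 adjusted over the list alone, with 8 at an unadjusted p under 0.05, 3 by DESeq2, 1 by limma and 25 with experiment 2 fitted alone. The other classical MYC targets had a median of −0.31 (camera adjusted p = 1.8e-06; adjusted p = 0.62 with an estimated correlation). By edgeR 0 of 48 passed over all genes and 1 adjusted over the list alone, with 7 lower at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma and 38 with experiment 2 fitted alone. G2/M and mitosis had a median of −0.31 (camera adjusted p = 6.0e-07; adjusted p = 0.69 with an estimated correlation). By edgeR 0 of 77 passed, whether over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05, 0 by DESeq2 or limma and 70 with experiment 2 fitted alone.

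The only lists that passed with an estimated correlation were epithelial markers and the serine and amino acid response. Epithelial markers had a median of −1.13, with 2 of 11 genes lower over all genes (KRT14 and KRT7, which fell by 1.68, SE 0.26) and 6 adjusted over the list alone. Only 11 of the 19 listed markers were tested, at a low mean log2 CPM of 1.42 and 1.46 against 2.15 and 2.29 in the controls. Their camera adjusted p was 1.8e-06, or 0.0383 with an estimated correlation, and 0.00474 by fry. The serine and amino acid response (ATF4) list had a median of −0.42 (camera adjusted p = 1.4e-05, or 0.0383 with an estimated correlation, and 0.0161 by fry). By edgeR 0 of its 27 genes passed over all genes, while 1 was higher and 9 lower adjusted over the list alone, 9 were lower at an unadjusted p under 0.05, 9 by DESeq2 and 2 by limma. Its transporters SLC7A5 and SLC1A5 had log2 fold changes of −0.80 (SE 0.16) and −0.75 (SE 0.15), not past the threshold (adjusted p = 0.0672 and 0.0629).

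Further lists passed with the preset correlation and not with an estimated one. Histone genes lay higher (median 0.87, camera adjusted p = 0.00274; adjusted p = 0.69 with an estimated correlation) but missed the threshold without a filter on low counts. This list was written as a check on poly(A) selection, and 20 of its 40 members were tested. Their mean log2 CPM was low, at 0.51 and 0.53 against −0.14 and −0.30 in the controls. Of these genes 0 passed by edgeR over all genes, with 3 higher at an unadjusted p under 0.05, 1 by DESeq2 and 9 with experiment 2 fitted alone. TGF-beta and SMAD targets had a median of 0.26 (adjusted p = 0.0140; 0.60 with an estimated correlation), where BAMBI rose by 1.04 (SE 0.17) over all genes and 2 genes adjusted over the list alone. The p53 targets and CDK inhibitors had a median of 0.23 (adjusted p = 0.00128; 0.60 with an estimated correlation), which was 0.36 without replicate 1 of the labelled MYC knockdown and 0.11 without replicate 2. NF-kB genes had a median of −0.18 (adjusted p = 0.00531; 0.69 with an estimated correlation) and missed the threshold with a stricter filter. Heat shock genes had a median of −0.21 (adjusted p = 0.0113; 0.61 with an estimated correlation) and cholesterol and fatty acid synthesis −0.23 (adjusted p = 0.00646; 0.69 with an estimated correlation). Cholesterol synthesis missed the threshold without replicate 2 of the labelled MYC knockdown (median −0.13, adjusted p = 0.141). Immune markers (median −1.32, adjusted p = 0.00993; 0.27 with an estimated correlation and 0.0303 by fry) missed it by limma and in unstranded counts, where their median was 0.02, and had a median of −0.74 without replicate 2 of the labelled MYC knockdown. Only 6 of the 20 listed immune markers were tested, at a low mean log2 CPM of 0.32 and 0.05 against 0.92 and 1.09 in the controls. Endothelial markers, 8 of 13 of them tested, had a median of −0.77 (adjusted p = 0.0118; 0.60 with an estimated correlation). Dedifferentiated melanoma genes had a median of −0.004, a mean of −0.28 and a test pointing down (adjusted p = 0.0162; 0.60 with an estimated correlation), with NGFR lower over all genes and 7 genes adjusted over the list alone. That list missed the threshold by limma, with a stricter filter, and without replicate 1 of the labelled MYC knockdown (median 0.07, adjusted p = 0.139), and its median was −0.08 without replicate 2 and −0.07 and 0.06 without control replicates 1 and 2. Of the other 18 lists, the MYC-MAX-MXD network (median −0.02, test up), the interferon list (0.05, down) and the extracellular matrix list (0.07, mean −0.02) had a median, mean or test that differed in sign, as did apoptosis regulators (−0.02, mean 0.02).

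**Figure D3:**
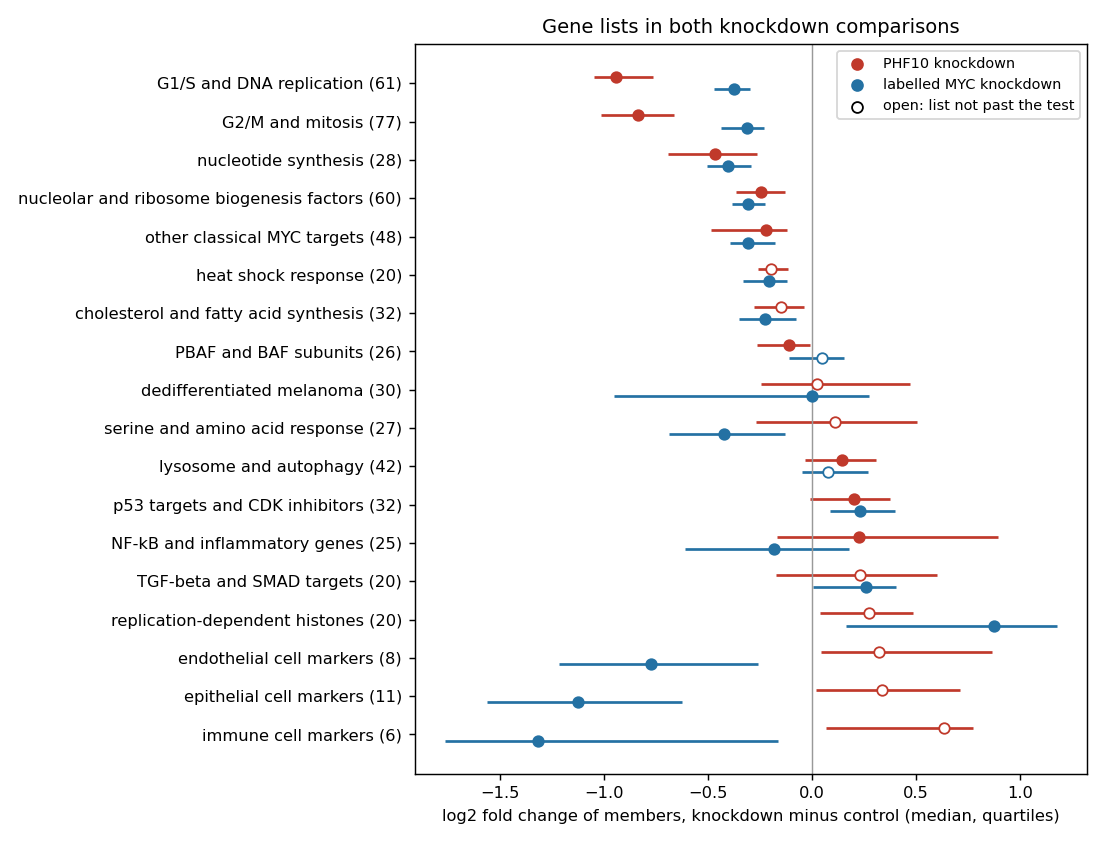
Median log2 fold change, after PHF10 knockdown and in the libraries labelled MYC knockdown, of each gene list that passed by camera in either comparison. Lists that passed in neither are not drawn. The G1/S and DNA replication list lies at −0.94 and −0.38, and the epithelial marker list at 0.34 and −1.13.

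Both comparisons were set side by side to ask whether PHF10 and MYC act on the same genes. Genes that rose both after PHF10 knockdown and in the libraries labelled MYC knockdown included PTHLH (log2 fold changes 3.39 and 1.72), ADAM19 (2.22 and 1.61), NTSR1 (2.07 and 2.52), SLC16A6 (1.81 and 1.31), PGM2L1 (1.15 and 1.33) and CSGALNACT1 (1.15 and 1.00). In all 20 genes rose in both comparisons, where 1.43 were expected from the 2 counts (Fisher's exact test, one-sided, p = 2.4e-18). Genes are not independent, so the Fisher p-values in this paragraph are descriptive only. The 2 counts also came from 1 fit with a shared spread per gene, which the expected count does not take into account. Genes that fell in both were COL5A3 (−1.89 and −2.13), WNK4 (−0.92 and −1.75), UCK2 (−0.91 and −0.73), TNS3 (−0.75 and −0.81), TGIF2 (−0.72 and −0.88) and ETS1 (−0.71 and −0.83). These 6 compared with 1.40 expected (Fisher's exact p = 0.00246). Genes that went opposite ways were KRT80 (1.65 and −1.87), TENM2 (1.75 and −1.08), CAV1 (0.67 and −1.50), LCP1 (1.18 and −2.33) and KRT7 (1.24 and −1.68), which rose after PHF10 knockdown and fell in the libraries labelled MYC knockdown. These 5 compared with 1.07 expected (Fisher's exact p = 0.00413). FGFR3 (−0.84 and 0.95), BAMBI (−0.61 and 1.04) and GNG2 (−0.47 and 0.77) went the other way, 3 against 1.86 expected (Fisher's exact p = 0.286). The shared counts were all 0 by edgeR without any 1 library of experiment 2, since 0 genes then passed in that experiment, with 1138 to 1414 at an unadjusted p under 0.05. With each experiment fitted alone 15 genes were higher in both (4.72 expected) and 20 lower (5.84 expected), while 6 were higher after PHF10 knockdown and lower in the other comparison, no longer more than the 4.97 expected (Fisher's exact p = 0.378), and 3 the reverse (5.55 expected). In those fits PHF10 knockdown moved past the threshold 4 of the 6 genes named as higher in both, 0 of the 6 named as lower in both (adjusted p = 0.0525 to 0.0858), KRT80 and TENM2 but not CAV1, LCP1 or KRT7, and 0 of FGFR3, BAMBI and GNG2. Without control replicate 1 of experiment 1, PHF10 knockdown no longer moved TGIF2, LCP1, KRT7, CAV1, FGFR3, BAMBI and GNG2 past the threshold (adjusted p = 0.0581 to 0.211). Without control replicate 2 this held for PGM2L1, TNS3, ETS1, LCP1, KRT7, CAV1, BAMBI and GNG2 (0.0680 to 0.248), without PHF10 knockdown replicate 3 for CAV1 (0.0588) and without replicate 4 for BAMBI (0.0615).

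As sets, the genes that PHF10 knockdown changed leaned the same way in experiment 2. The 661 that fell had a median log2 fold change of −0.23 there, negative in 79.0% (camera adjusted p = 1.3e-11, or 0.0322 with an estimated correlation). The 508 that rose had one of 0.26, positive in 71.3% (adjusted p = 1.9e-11, or 0.00967). The 52 genes that rose in the libraries labelled MYC knockdown had a median of 0.41 after PHF10 knockdown, positive in 78.8% (adjusted p = 1.5e-17, or 0.00435). The 39 that fell there had a median of 0.01, negative in 48.7%, with a test pointing down (adjusted p = 0.238). Across all genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.186 and Spearman's rho of 0.257. Among the 11544 genes with a mean of at least 5 CPM these were 0.304 and 0.365. Over all 18450 genes, differences between 2 replicates of 1 group also correlated with the other experiment's fold changes (9 pairs). Those correlations reached 0.175 in size for Pearson's r, little below 0.186, and 0.195 for Spearman's rho, against 0.257. None was computed for the 11544 genes.

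**Figure D4:**
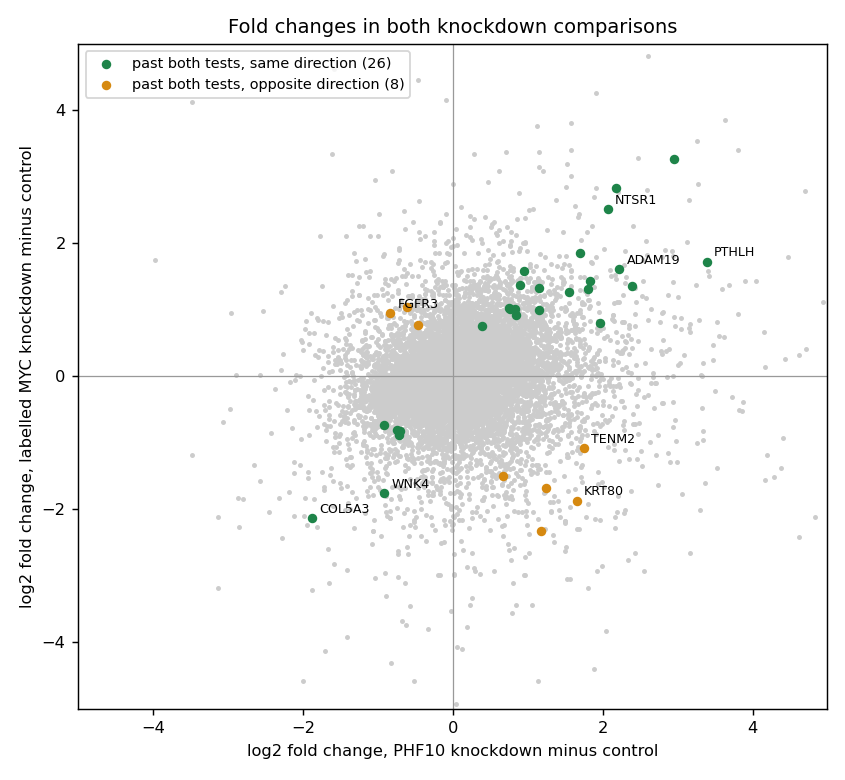
Log2 fold change of each tested gene after PHF10 knockdown (horizontal) against that in the libraries labelled MYC knockdown (vertical). Of the genes past the threshold in both, 26 lie in the quadrants of equal sign and 8 in the others, and 15 genes lie outside the axes of ±5.

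The difference of the 2 responses was tested directly, although knockdown and experiment cannot be told apart in it. KRT80 differed by 3.52 on the log2 scale (SE 0.25, adjusted p = 0.00177), LCP1 by 3.51 (SE 0.32), KRT7 by 2.92 (SE 0.36), KRT81 by 2.97 (SE 0.50), IGFN1 by 4.31 (SE 0.71) and MYPN by 3.38 (SE 0.57), all higher after PHF10 knockdown. SLC7A5 differed by 2.25 (SE 0.22) and SLC3A2 by 1.28 (SE 0.17). PALM differed by −2.31 (SE 0.38), TUBB4A by −2.03 (SE 0.32), ZNF853 by −1.79 (SE 0.29), FGFR3 by −1.78 (SE 0.19) and CCDC113 by −1.74 (SE 0.25). In all 48 genes were higher and 23 lower. KRT80 alone of these passed without any 1 library, and the counts were 7 and 1 without control replicate 1 of experiment 1, 2 and 0 without control replicate 2, 93 and 49 without PHF10 knockdown replicate 1, and 79 and 43 without replicate 2. Without any 1 library of experiment 2 they were 1 to 3 higher and 0 lower, with 1317 to 1398 genes at an unadjusted p under 0.05, while DESeq2 gave 363 and 270 on all libraries and limma 31 and 25.

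Of the lists, epithelial markers differed by a median of 1.05 (1 of 11 genes over all genes and 5 adjusted over the list alone; camera adjusted p = 1.0e-07, or 0.0164 with an estimated correlation), and by 1.70 without replicate 1 of the labelled MYC knockdown. The serine and amino acid response differed by 0.36 (2 of 27 genes over all genes and 8 adjusted over the list alone; adjusted p = 2.2e-07, or 0.0164 with an estimated correlation), and by 0.55 without control replicate 1 of experiment 1. G1/S and DNA replication differed by −0.55 (adjusted p = 6.0e-15; 0.55 with an estimated correlation) and G2/M and mitosis by −0.54 (adjusted p = 3.6e-12; 0.79 with an estimated correlation), the latter by −0.32 without control replicate 2 of experiment 1. For nucleotide synthesis (−0.06), other classical MYC targets (−0.02) and ribosome biogenesis factors (0.04) the difference did not pass (adjusted p = 0.443, 0.523 and 0.571). In all 11 lists passed, 2 of them with an estimated correlation and 3 by fry.

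The remaining lists of the difference passed only with the preset correlation or by fry. NF-kB genes differed by 0.48 (adjusted p = 7.9e-06; 0.55 with an estimated correlation), by 0.73 without control replicate 1 of experiment 1 and by 0.27 without its replicate 2. Immune markers, with 6 tested genes of low CPM, differed by 2.42 (adjusted p = 0.00248; 0.13 with an estimated correlation and 0.0163 by fry). Endothelial markers differed by 1.49 (adjusted p = 0.00180; 0.53 with an estimated correlation), and by 0.79 without PHF10 knockdown replicate 1. Cytosolic ribosomal proteins differed by 0.25 (adjusted p = 0.00598; 0.94 with an estimated correlation), by 0.61 without control replicate 2 of experiment 1, and missed the threshold without PHF10 knockdown replicate 3 or 4 or control replicate 1 (medians 0.15, 0.14 and −0.05, adjusted p = 0.155, 0.176 and 0.436). PBAF and BAF subunits differed by −0.20 (adjusted p = 0.0161; 0.52 with an estimated correlation) and missed it without control replicate 2 of experiment 1 (median −0.09, adjusted p = 0.112). The PBAF and BAF list includes PHF10 itself and was not tested without it. Histones differed by −0.78 (adjusted p = 0.0386; 0.94 with an estimated correlation) and by −1.26 without control replicate 2 of experiment 1. They missed the threshold without PHF10 knockdown replicate 3 (0.207) or 4 (0.176), control replicate 1 of experiment 1 (0.977, with a median of 0.17) or control replicate 2 of experiment 2 (0.0674). Neural crest and neuronal genes differed by −0.41 (adjusted p = 0.0359; 0.52 with an estimated correlation) and by −0.22 without control replicate 1 of experiment 1. They missed it without PHF10 knockdown replicate 4 (0.121), replicate 2 of the labelled MYC knockdown (0.0599) or control replicate 1 of experiment 2 (0.0843). In 3 lists the median and the test of the difference disagreed in sign, glycolysis (0.07, test down), TGF-beta and SMAD targets (0.03, test down) and cholesterol and fatty acid synthesis (−0.01, test up), and in the MYC-MAX-MXD network the median (−0.17) and the mean (0.03) did.

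The controls of the 2 experiments were compared to see how far the experiments can be set side by side. In experiment 2 MMP9 was higher by 6.96 on the log2 scale (SE 0.29), IL1A by 4.09 (SE 0.43), CXCL3 by 3.68 (SE 0.30) and LIF by 2.43 (SE 0.20). Of the 25 tested NF-kB and inflammatory genes 24 were higher, over all genes and adjusted over the list alone, with a median of 2.43 (camera adjusted p = 3.6e-50, or 0.0393 with an estimated correlation). PHF10 itself was higher by 1.70 (SE 0.12), and BRCA1 by 1.41 (SE 0.14). OLFML3 was lower by a log2 difference of −4.57 (SE 0.38) and CADM3 by −4.50 (SE 0.31). Type I interferon genes had a median of −2.80 (adjusted p = 3.7e-07; 0.68 with an estimated correlation), which was −0.95 without control replicate 1 of experiment 1, and HLA genes one of −1.23 (adjusted p = 1.4e-07; 0.40 with an estimated correlation), which was −0.32 without it. Genes of G1/S and DNA replication had a median of 0.56 (18 of 61 higher over all genes and 27 adjusted over the list alone; adjusted p = 3.3e-11; 0.56 with an estimated correlation). Those of G2/M and mitosis had one of 0.70 (19 of 77 higher over all genes and 31 adjusted over the list alone; adjusted p = 3.8e-13; 0.60 with an estimated correlation).

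In all 1485 genes were higher and 1217 lower in experiment 2, or 1028 and 1690 with upper-quartile factors, which took the share of higher genes from 55.0% to 37.8%. Those counts were 572 and 418 without control replicate 1 of experiment 1, 679 and 743 without its replicate 2, 373 and 186 without control replicate 1 of experiment 2, and 387 and 210 without its replicate 2.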

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

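Of the tests that weigh patterns in this part, those of a second structure among the PHF10 knockdown libraries and of exchanged labels were chosen after the result was seen.

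TBXAS1 in PHF10 knockdown replicate 3 lay far from the other 3 libraries, at 2.29 log2 CPM against 2.37 to 2.38, a gap of 0.924 of the whole range, past Dixon's critical value for 4 values. The gap is small in absolute terms, and it was the only one among 85 groups of 4 values tested, where 4.25 would be found by chance (1 in 20).

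The responses to PHF10 knockdown and in the labelled MYC knockdown differed for 71 genes by a direct test, 48 higher and 23 lower for PHF10. The difference of the list medians was 0.361 for the serine and amino acid response (ATF4) and 1.05 for epithelial markers, and both lists passed with an estimated correlation. What picked out these 3 results was the test of a difference between groups, in which knockdown and experiment cannot be told apart.

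The spread between replicates was larger in experiment 1, at 26.8% against 3.39%. Thinning experiment 2 to the depth of experiment 1 gave 3.29%, so lower depth is excluded as the cause. Taking the split of the interferon genes as a term left 21.8%, so that split is excluded as the whole cause. The difference of PHF10 knockdown replicates 1 and 2 and that of replicates 4 and 3, which share no library, correlated across genes with r of 0.681, consistent with a second structure among these 4 libraries. No biological explanation was tested, and neither was the origin of the replicates.

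MYC mRNA did not separate the groups of experiment 2. The difference of the first library labelled MYC knockdown from its control and that of the second, which share no library, correlated across genes with r of 0.638, which excludes an exchange of 2 labels. An exchange of all labels between the groups would leave this r unchanged, so it is left open. The fold change of MYC from reads on either strand was −0.66 against −0.46 from the stranded reads, a move in the direction that a loss of reads to overlapping genes predicts. The move stayed within the limit of 1 SE set beforehand as evidence against this explanation, but that SE measures libraries and not 2 ways of counting the same libraries, so the explanation is left open. Regrowth of MYC mRNA by 72 h, or an effect on protein only, was not tested.

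The G1/S and DNA replication list lay lower after PHF10 knockdown and in the libraries labelled MYC knockdown with the preset correlation, but not with an estimated one (adjusted p = 0.41 and 0.60), and by fry only after PHF10 knockdown (0.0151, against 0.231). Its median fold change was −0.79 in the weaker part of the split of experiment 1 and −1.14 in the other, so the split is excluded as the cause. The largest median difference between 2 libraries of 1 group was 0.525 in experiment 1, against a fall of 0.94, and 0.133 in experiment 2, against a fall of 0.38. The controls of the 2 experiments differed by 0.56 on this list, less than the fall in experiment 1. Its mean log2 CPM was 4.36 to 4.86 in the PHF10 knockdown libraries and 5.45 and 5.55 in their controls. That fall thus exceeded the differences seen between libraries of 1 group. With only 2 controls, whose origin in separate cultures is not given, these values cannot bound variation between cultures, which is left open. In experiment 2 the fall lay under 0.56 and the replicates may be technical, so variation between cultures is left open there too. Progress through the cell cycle was not measured.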

How the results depend on the processing

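The split of experiment 1, as a term or as parts, was chosen after seeing the data, and the cause of each change here was not tested unless named. Higher and lower genes are given in that order. After PHF10 knockdown they were 1032 and 1133 by DESeq2, 1135 and 1237 with no filter, 23 and 27 with each experiment alone, 37 and 31 against a fold of 1.5, 1073 and 1394 with the split as a term, and 145 and 382 in its higher part only. For the labelled MYC knockdown they were 354 and 366 by DESeq2, 128 and 80 by limma, 453 and 458 with no filter, 3790 and 3989 with each experiment alone, 2 and 7 against a fold of 1.5, and 265 and 293 with the split as a term. For the difference they were 363 and 270 by DESeq2, 31 higher by limma, 585 and 333 with no filter, 5 and 0 against a fold of 1.5, and 284 and 205 with the split as a term. Genes past the threshold in both, as lower, higher, PHF10 lower with MYC higher and the opposite, were 80, 125, 14 and 39 by DESeq2, 98, 156, 20 and 72 with no filter, 82, 101, 16 and 26 with the split as a term, and 0, 1, 0 and 1 against a fold of 1.5. By limma 32 were higher in both, with each experiment alone 20 were lower, and with a log2 fold change of at least 1 there were 1 lower (0.38 expected), 11 higher and 0 PHF10 lower with MYC higher.

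Same-numbered replicates deviated together by r of 0.484 and −0.297 in experiment 1 and −0.0309 in experiment 2, so the numbers do not pair the samples. With the replicate number as a block 0 genes were higher and 0 lower for the labelled MYC knockdown by edgeR (3036 at an unadjusted p under 0.05), 1 and 0 for the difference, and 0 in each pair of directions. The block also took the ribosomal protein median after PHF10 knockdown to −0.16 and the interferon median to 1.11, and it was not run for the controls.

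With no filter MYC mRNA after PHF10 knockdown passed at −0.83. After PHF10 knockdown 16 lists passed with no filter, 16 with the block, 18 with the split as a term, 0 with an estimated correlation and 1 by fry, and for the labelled MYC knockdown 2 with an estimated correlation and 3 by fry. The set of genes lower in the labelled MYC knockdown had a median after PHF10 knockdown of −0.10 by DESeq2, −0.025 with no filter, −0.17 with each experiment alone and −0.15 with the split as a term.

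With 1 library left out, genes past the threshold were 68 to 646 higher and 127 to 741 lower after PHF10 knockdown, 0 and 0 by edgeR for the labelled MYC knockdown, 1 to 93 and 0 to 49 for the difference, and 373 to 679 and 186 to 743 between the controls. Those in both were 0 to 14 lower, 0 to 40 higher, 0 to 7 PHF10 lower with MYC higher, and 0 to 10 the opposite, and 9 to 19 lists passed after PHF10 knockdown. After PHF10 knockdown the ribosomal protein median ranged from −0.17 to 0.53 and the interferon median from −1.18 to 2.04 (without control replicates 1 and 2 in turn at the ends), and that of the genes lower in the labelled MYC knockdown from −0.28 to 0.0614.

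Of the main results 274 values kept their direction and side of the threshold or stayed within 1.5 times, 138 counts moved further and 6 newly passed. Of single genes and lists 5735 values kept their side of the threshold, 521 newly passed, 684 no longer did and 4 turned sign with a threshold passed on either side. Over all settings the medians of 14 of 34 lists lay on both sides of 0 after PHF10 knockdown, 0 of them past the threshold, and of 6 for the labelled MYC knockdown, 2 of them past it (dedifferentiated melanoma and immune markers). The controls and the difference were not run with each experiment alone, the controls not against a fold of 1.5, and sets of 0 genes gave no value. What depth limits among genes of few reads was not tested.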

Other observations

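The test of a second structure among the PHF10 knockdown libraries was chosen after the result was seen, as were all genes and lists named in this part.

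Interferon-stimulated genes split the libraries of experiment 1 into 2 parts that crossed the groups. ISG15 measured 322, 270, 9.08 and 26.1 CPM in PHF10 knockdown replicates 1 to 4, and 563 and 29.3 CPM in control replicates 1 and 2. MX1 measured 672, 385, 9.82 and 77.7 CPM, and 769 and 69.6 CPM in the controls. All 43 genes of the type I interferon list were higher in PHF10 knockdown replicates 1 and 2 and in control replicate 1 than in the others, with a median difference of 3.00 on the log2 scale between the PHF10 knockdown libraries and 3.12 between the controls. Replication-dependent histones were higher by 1.40 and 1.59 in the same libraries and HLA genes by 0.66 and 1.04, while cytosolic ribosomal proteins differed by −0.60 and −0.66.

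A second contrast ran between PHF10 knockdown replicates 1 and 4 and replicates 2 and 3. STC1 measured 407, 115, 88.9 and 250 CPM in replicates 1 to 4, and MITF 46.7, 21.9, 20.4 and 38.2 CPM. Endothelial markers had a median difference of 1.42 on the log2 scale between these pairs.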
